A study of Mus musculus with 24 samples.

How the data were processed

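RNA sequencing libraries from 24 preparations of mouse brain cells were analysed, 3 in each of 8 groups defined by cell type (microglia or astrocytes), injection (saline or lipopolysaccharide, LPS) and Serpine2 genotype (control or knockout). Per the labels' protocols, mice were perfused with phosphate buffered saline, microglia were taken from whole brain by douncing and Percoll, and astrocytes from cortex by papain. Both cell types were then bound to antibody-coated dishes (immunopanning), and total RNA was turned into libraries with Ovation V2 and NEBNext Ultra kits. The deposited values were whole-number read counts per Ensembl gene identifier, with no normalisation by the authors, as checked on the tables themselves. Per the submitters' processing notes, reads were aligned with STAR 2.6.0c and counted with HTSeq, whose version was not given. The same notes named GRCm38 and GRCm39 without saying which build served which table, and they gave no strand setting, counting mode or annotation release. Per the deposited files, microglia had 53700 identifiers and astrocytes had 55487, of which 52404 were shared. Symbols were found in a reference table for 52093 microglia and 55141 astrocyte identifiers. Coordinates are those of GENCODE release 21 on GRCm38.

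Gene counts were analysed within each cell type, 12 libraries at a time, with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr on the groups, with a minimum count of 10 and a minimum total of 15, which left 22230 genes in microglia and 18188 in astrocytes. Libraries were scaled by TMM, a robust quasi-likelihood model with 1 mean per group was fitted, and contrasts were tested two-sided with glmQLFTest. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 14 comparisons were, in each cell type, knockout against control in saline, in LPS and averaged over both, LPS against saline in each genotype, and the difference between genotypes in the LPS response, plus the microglial minus the astrocytic knockout effect in saline and in LPS. Those last comparisons used all 24 libraries and 24607 genes, and cell type there went together with brain region, preparation and gene annotation. CPM are gene counts scaled to library size with the TMM factors, and log2 CPM used a prior count of 2. Standard errors (SE) are those of the fitted log2 fold change, and standard deviations (SD) are over the 3 libraries of a group. Intervals and tests cover the spread between these libraries, and reads without molecular identifiers are not independent molecules.

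A total of 23 gene lists and 14 lists of cell type markers were written before the data were examined, as were the comparisons, the tests, the rule for naming genes and most alternatives. The gene lists were tested with camera from limma 3.58.1, which asks whether a list moved more than the other genes, at a preset inter-gene correlation of 0.01 and with adjustment over the lists of a comparison. The same lists were also tested with the correlation estimated from the data and with fry, a directional test of a list on its own. Members past the threshold were counted over all genes and adjusted over the list alone. Lists with fewer than 5 tested members were left out of a comparison. Marker lists were averaged as log2 CPM per library and compared by an exact two-sided permutation test, whose smallest p for 3 against 3 libraries is 0.1, so that no marker score could pass 0.05. Camera on the marker lists was added after the data had been seen.

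Genes were named by rule. For effects of the knockout and for differences, these were up to 10 called genes per direction with the smallest p. For LPS responses they were up to 10 called genes per direction with the largest fold change among those averaging at least 8 CPM over the 12 libraries. Members of a list were also named in describing that list, as were Serpine2 and the sex-linked transcripts. Predicted genes were counted and not named. Reads may be split between near-identical copies, and the values of Lyz1 and Lyz2, Ifit3 and Ifit3b, the H2 class I genes, Saa1, Saa2 and Saa3, the Gbp genes, Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt are uncertain for that reason. Overlapping and antisense genes are uncertain too, since no strand setting was stated.

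The alternatives were RLE factors in place of TMM, DESeq2 1.42.0 in place of edgeR, no filter on low counts, a stricter minimum count of 50, sex from the labels as a covariate, the replicate number as a block, a fit of only the groups compared, and each library left out in turn. Alternatives added after the data had been seen were sex read from transcripts, the share of reads outside annotated genes as a covariate, the neutrophil marker score as a covariate, the antimicrobial list without its neutrophil markers, the astrocyte fit without the third LPS library of both genotypes, and each library left out for camera on the marker lists and for the marker scores. The labels speak of sibling pairs without saying that replicate numbers mark them. The names of the deposited astrocyte tables carry a number that may stand for a day, and control and knockout libraries with the same injection and replicate number share it, except the third LPS libraries. Whether libraries with the same number deviated together was therefore checked on the data. Every same-number correlation of deviations exceeded 0.1 for knockout against control LPS astrocytes (0.554, 0.286 and 0.595) and for LPS against saline knockout astrocytes (0.197, 0.248 and 0.160), and in no other comparison, saline astrocytes (−0.301, 0.0640 and 0.0910) included. Only there were the numbers treated as marking pairs, a choice that rests on the correlations alone and, for the third LPS libraries and for LPS against saline, goes against the numbers in the names. For LPS against saline the block was a common effect per number over all libraries of the cell type, not a pairing within a genotype. Single pairs elsewhere also deviated together, such as saline control 1 and saline knockout 1 microglia (0.697, beside −0.169 and −0.154 for numbers 2 and 3).

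The whole chain was tested on simulated data with the dispersions and library sizes of the real libraries. Gene means were taken over all libraries of a cell type, and 200 genes with a mean count above 1 were changed. With edgeR, comparisons of 3 against 3 libraries recovered 0% to 3.03% of genes changed 1.5-fold, 0% to 15.2% of those changed 2-fold and 42.2% to 86.4% of those changed 4-fold. Differences of responses recovered none of the 1.5-fold and 2-fold changes and 10.9% to 35.4% of the 4-fold changes. False calls made up 0% to 20.7% of edgeR's calls and 15.6% to 33.8% of DESeq2's, above the nominal share in part of the comparisons. For microglia in saline, knockout against control, edgeR recovered 74.2% of 4-fold changes. Camera called a list shifted 1.5-fold in 12 of the 14 comparisons and in 10 with an estimated correlation. It missed the shifted list in 2, the astrocyte difference of LPS responses (adjusted p 0.773) and the saline difference between cell types (adjusted p 0.35). None of the 19 unshifted lists was called in any comparison. The simulated genes varied independently of each other, so this does not show how often camera calls lists whose genes vary together. Other splits of the real libraries did give such calls (below).

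No protein, single-cell or raw read data were used here. The dose of LPS, the time after injection and the deleted exons of Serpine2 were not stated in the labels. The number of reads behind a library was taken as its gene counts, and reads on no gene, on several genes or at several places were used only to describe the libraries.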

Results

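The libraries came from microglia and astrocytes immunopanned from adult mice without Serpine2 and from littermates that kept 1 or more working alleles, called controls here. Mice had received saline or LPS, a component of bacterial outer membranes that sets off innate immune responses. Gene counts per library ran from 4506142 to 13621776 in microglia and from 10944765 to 25135252 in astrocytes, with 12 libraries of each cell type and 3 in each group. Microglia libraries detected 28845 to 33076 genes and astrocyte libraries 22272 to 25177. In astrocyte libraries the 10 most abundant genes, led by mt-Rnr2, CT010467.1 and mt-Rnr1, the first and last of them mitochondrial ribosomal RNAs, took 47.7% to 66.4% of gene counts, against 7.91% to 19.4% in microglia. The sex-linked transcripts matched the label in 23 of the 24 libraries. The microglia LPS control 1 library, labelled female, had 73 counts of Xist and 251 of the Y-linked Ddx3y, the male pattern.

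Serpine2, which encodes the serine protease inhibitor protease nexin-1 (ENSMUSG00000026249, chromosome 1, 79794197 to 79861180, minus strand), was lower in every knockout library than in every control library of the same cell type and injection. In microglia it averaged 68.4 ± 25.6 CPM in saline controls and 19.5 ± 1.62 in saline knockouts, and 68.5 ± 19.4 against 18.3 ± 1.23 after LPS (SD, n = 3 each). Astrocytes held 141 ± 42.4 CPM in saline controls and 19.2 ± 2.68 in saline knockouts, and 88.6 ± 16.3 against 17.2 ± 1.02 after LPS (n = 3 each). Reads on the gene therefore remained in the knockouts, and which exons were deleted was not stated. The microglia preparations also held neuron transcripts (below), so these levels are those of the preparations. The log2 fold change was −2.88 (SE 0.26, edgeR adjusted p 5.24e-05) in saline astrocytes and −2.36 (SE 0.25, adjusted p 0.000747) in LPS astrocytes. Averaged over both injections, Serpine2 fell by 2.62 (SE 0.18, adjusted p 9.11e-07) in astrocytes and by 1.86 (SE 0.19, adjusted p 0.00221), or 3.63-fold, in microglia. Within one injection the microglial value missed the threshold in edgeR, at −1.82 in saline (SE 0.27, adjusted p 0.191) and −1.90 in LPS (SE 0.27, adjusted p 0.118), and passed it in DESeq2 (adjusted p 6.19e-06 and 4.95e-07). Without the saline control 2 library the saline value was −1.98 (adjusted p 0.0244), and without the LPS control 1 library the LPS value was −2.09 (adjusted p 0.0425). The knockout effect on Serpine2 in microglia minus that in astrocytes was 1.11 in saline (95% interval 0.38 to 1.84, edgeR unadjusted p 0.00456), not called over all genes (adjusted p 0.761), and 0.44 in LPS (−0.30 to 1.17, unadjusted p 0.233, adjusted p 1).

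**Figure D1:**
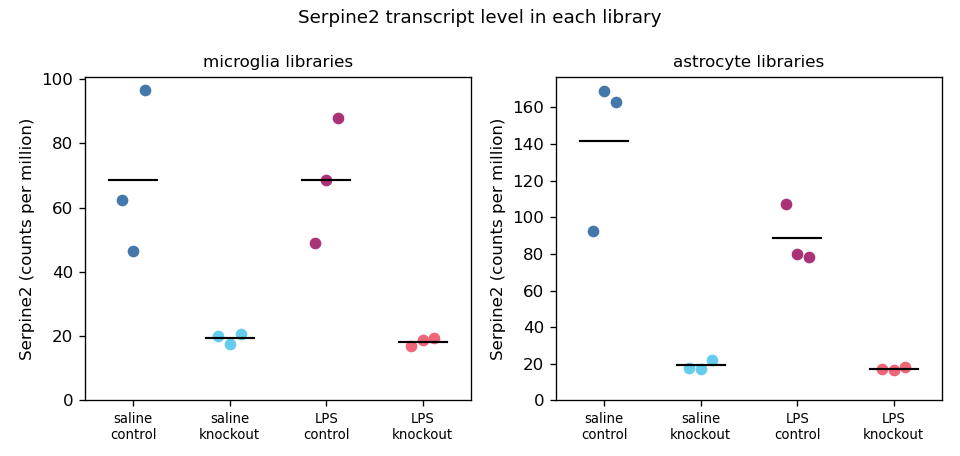
Serpine2 level in CPM in each of the 24 libraries by cell type, injection and genotype, each point a library and each bar the mean of 3. Knockout libraries averaged between 17.2 and 19.5 CPM in all 4 conditions, below every control library.

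Whether loss of Serpine2 altered microglia without LPS, and antimicrobial genes above all as the series title has it, was asked in the saline groups. Genes for antimicrobial proteins of neutrophils, most of them stored in granules, had higher means in knockout microglia. S100a8, a subunit of the metal-binding protein calprotectin, averaged 510 ± 184 CPM in knockouts and 187 ± 14.1 in controls, 2.72-fold more (log2 1.44, SE 0.33, SD, n = 3 each). The cathelicidin gene Camp stood at 118 ± 26.1 against 47.2 ± 8.80 CPM (2.51-fold, log2 1.33, SE 0.32), and the iron-scavenging lipocalin Lcn2 at 127 ± 33.9 against 56.1 ± 3.07 CPM (2.27-fold, log2 1.18, SE 0.28). Lyz2, the lysozyme gene of myeloid cells, was at 403 ± 73.0 against 233 ± 30.1 CPM (log2 0.79, SE 0.20), Ngp at log2 1.14 (SE 0.31) and Mpo at 1.54 (SE 0.42). Members without that shift included Rnase4 (−0.27), Cyba (−0.24) and Saa3 (−0.13). Of the 31 antimicrobial genes tested, 24 were higher in knockouts, with a median log2 fold change of 0.91, and camera placed the list above other genes (adjusted p 3.74e-33, 0.00663 with an estimated correlation, 0.0787 with fry). No member was called over all genes, and 15 were, all higher, when adjusted over the list alone. Neutrophil markers moved with them, 11 of 12 higher at a median of 0.93 for the 7 outside the antimicrobial list and 1.13 for all (camera adjusted p 3.63e-27, 0.0117 with an estimated correlation), while Csf3r was flat (−0.10). With the score of the 7 neutrophil markers outside the list as a covariate, the antimicrobial median was 0.47. The list was then called at the preset correlation (camera adjusted p 2.78e-05) and not at the estimated one (0.452). Without its 5 neutrophil markers the list kept its call at both, with a median of 0.82 and 19 of 26 genes higher. Those 26 still include Lcn2 and Mpo.

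**Figure D2:**
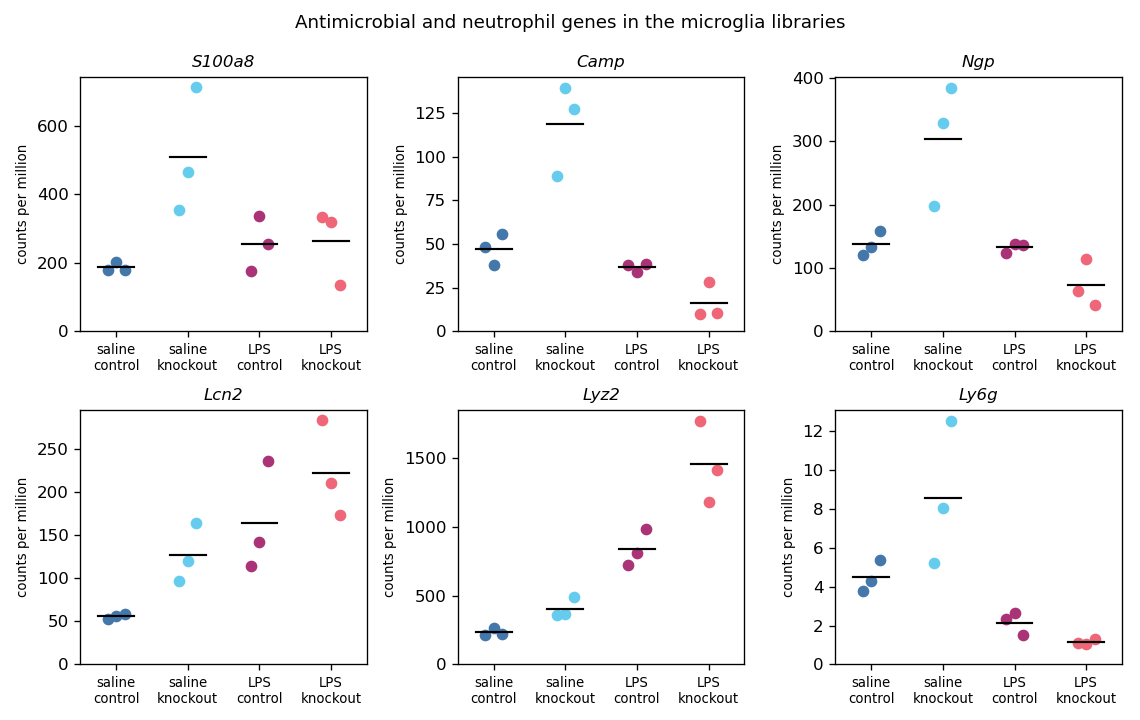
Levels in CPM of S100a8, Camp, Ngp, Lcn2, Lyz2 and the neutrophil marker Ly6g in the 12 microglia libraries, each point a library and each bar the mean of 3. In saline the knockout means lie above the control means for all 6 genes, and after LPS Camp, Ngp and Ly6g lie lower in knockouts.

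Other groups of genes in saline knockout microglia moved less, and none held with an estimated correlation. Monocyte markers were higher at a median log2 of 0.68 (camera adjusted p 6.59e-09, 0.0707 estimated, and 1.06 without saline knockout 2), as were pan-reactive astrocyte genes (0.46, 6.06e-05, 0.39 estimated), a list that shares Lcn2. Genes of homeostatic microglia were lower, with 0 of 20 higher and a median of −0.26 (adjusted p 6.06e-05, 0.77 estimated), and so were the overlapping microglia markers (−0.28, 0.00229, 0.573 estimated). The microglia marker call was lost without saline control 1 (0.01, adjusted p 0.469), saline knockout 2 (−0.08, 0.212) or saline knockout 3 (−0.05, 0.273), and the median was −0.74 without saline knockout 1. MHC class II genes (0.24, adjusted p 0.00567), cell cycle genes (0.14, 0.00394), astrocyte homeostasis genes (0.15, 0.0349) and interferon-stimulated genes (0.09, 0.0161) were called higher at the preset correlation and not at the estimated one (0.77 for each). Vascular fibroblast markers (0.28, adjusted p 0.0266) and astrocyte markers (0.20, 0.0389) behaved alike (0.573 estimated for both), and each lost the call without any 1 of 3 libraries, saline control 2 and saline knockout 1 among them. The plasminogen and thrombin genes, on which protease nexin-1 acts, were not called (0.02, adjusted p 0.358), nor were the other serpins (−0.10, 0.98) or immediate early and dissociation stress genes (−0.11, 0.478), and in all 16 of the 23 lists were not called. Oligodendrocyte (−0.03, 0.96), neuron (−0.03, 0.819) and erythrocyte markers (0.13, 0.742) were not called either. Gene by gene, edgeR called 0 genes in this comparison, with 351 at an unadjusted p under 0.05 where 1112 would be the chance number, and DESeq2 called 1.

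After LPS no gene other than Serpine2 was called between knockout and control microglia by edgeR or DESeq2. With an estimated correlation no list was, and at the preset correlation 4 of 10 splits of these libraries gave as many lists. Cell cycle genes had higher means in knockouts, 18 of 20 with a median log2 fold change of 0.66, and Top2a stood at 62.1 ± 41.8 against 30.4 ± 8.27 CPM (log2 1.04, SE 0.40, SD, n = 3 each). LPS-induced cytokines and chemokines (0.35) and interferon-stimulated genes (0.29) were higher too, and homeostatic microglia genes lower (−0.35). Antimicrobial genes as a list were not called (median 0.14, mean −0.01, test upward, adjusted p 0.958). Within it Lyz2 was higher at 1455 ± 295 against 838 ± 130 CPM (log2 0.80, SE 0.20) and Camp lower at 16.4 ± 10.3 against 37.0 CPM (−1.21, SE 0.33), the 2 members called when adjusted over the list alone. Camera called 11 of 23 lists at the preset correlation, cell cycle (adjusted p 2.83e-12), interferon (4.02e-06), homeostatic (4.02e-06) and cytokines (0.000139) among them, and 0 at the estimated one (0.364, 0.435, 0.529 and 0.364). The others were pan-reactive astrocyte genes (0.45, adjusted p 0.000554, 0.364 estimated), A1 reactive astrocyte genes (0.27, 0.00192, 0.364), oxidative phosphorylation (0.15, 0.0125, 0.55), NF-kB targets (0.19, 0.0159, 0.587), MHC class II (−0.30, 0.02, 0.529), MHC class I (0.11, 0.0234, 0.611) and serpins (0.28, 0.0234, 0.529). Monocyte (0.61, adjusted p 0.000124) and microglia markers (−0.37, 6.9e-05) were called at the preset correlation and not the estimated one (0.652 for both). The monocyte call rested on LPS knockout 1, without which the median was 0.32 (adjusted p 0.542) and the difference in mean log2 CPM −0.02 in place of 0.41. Microglia markers lost the call without LPS knockout 3 (−0.29, adjusted p 0.081) and otherwise ran from −0.66 to −0.18. The antimicrobial list was called without the LPS control 3 library (adjusted p 0.00434) and without the LPS knockout 3 library (0.024). Gene by gene, edgeR called 0, with 335 at an unadjusted p under 0.05, and DESeq2 called 1, Serpine2.

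Averaged over saline and LPS, Serpine2 was the only gene that edgeR called in microglia, with 449 at an unadjusted p under 0.05 and 4 called by DESeq2. Antimicrobial genes were higher in knockouts, 25 of 31 with a median of 0.26, and 8 were called when adjusted over the list alone. The list passed at the preset correlation (adjusted p 6.48e-15) and not at the estimated one (0.0833). Cell cycle (0.42, adjusted p 4.22e-11, 0.3 estimated), pan-reactive (0.40, 2.05e-07, 0.156) and interferon-stimulated genes (0.24, 1.9e-06, 0.425) were higher and homeostatic genes lower (−0.31, 3.3e-09, 0.425) on the same terms. Cytokines (0.19, adjusted p 0.0185, 0.571 estimated), A1 genes (0.10, 0.0185, 0.473) and oxidative phosphorylation (0.08, 0.0255, 0.653) completed the 8 lists. Of the cell type markers, monocyte (0.58, adjusted p 7.74e-11, 0.084 estimated) and neutrophil markers (0.65, 1.23e-08, 0.149, and 0.42 without LPS knockout 1) were higher and microglia markers lower (−0.33, 5.41e-07, 0.356), all at the preset correlation only. The microglia marker median was −0.18 without saline control 1, −0.20 without saline knockout 3, −0.22 without LPS control 3 and −0.56 without saline knockout 1. Border macrophage (0.23, adjusted p 0.0165) and vascular fibroblast markers (0.18, 0.0434) were called higher too (0.5 estimated for both), and each lost the call without any 1 of several libraries, saline control 1 among them.

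LPS raised and lowered single genes in microglia preparations of both genotypes. In control microglia Saa3, an acute phase protein, rose 410-fold, from 2.02 ± 0.625 to 865 ± 466 CPM (log2 8.68, SE 0.48, SD, n = 3 each). The scavenger receptor gene Marco rose 392-fold (8.61, SE 0.82), Acod1, whose enzyme makes the antimicrobial metabolite itaconate, 95.4-fold (6.58, SE 0.62) and Il1b 12.2-fold (3.61). Acp5 (5.50), Gzma (5.09), Wfdc17 (4.46), Msr1 (3.88), Siglec1 (3.62) and Hmox1 (3.34) also rose. The purinergic receptor P2ry12, a marker of resting microglia, fell 6.68-fold from 383 ± 3.41 to 57.3 ± 23.6 CPM (−2.74, SE 0.36), with Gpr34 (−2.39), Hpgd (−2.08), Slc2a5 (−1.97), Tgfbr1 (−1.93) and P2ry13 (−1.72). EdgeR called 117 genes higher and 11 lower. Hpgd, Slc2a5 and Tgfbr1 lost the call without one or another library, and 13 of the 16 genes named here kept it whichever library was left out. Slc2a5 lost it also with sex from the labels (adjusted p 0.193) or the replicate block (0.0564), and Tgfbr1 with sex from the labels (0.0711).

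In knockout microglia the same response was called for 254 genes, of which 29 fell. Saa3 rose 656-fold to 1262 ± 359 CPM (log2 9.36, n = 3), Marco by 8.96, Acod1 5.50, Acp5 5.13, Msr1 4.95, Gzma 4.73, Fcgr4 3.54, Ccl5 3.52 and Siglec1 3.42, with Lgals1 between them. Camp fell from 118 ± 26.1 to 16.4 ± 10.3 CPM (−2.89, SE 0.35) and Ngp from 303 ± 95.9 to 73.2 ± 36.6 (−2.06, SE 0.32), along with P2ry12 (−2.76), Hpgd (−2.55), Gpr34 (−2.46), Slc2a5 (−2.33), Siglech (−2.32), Tgfbr1 (−1.86) and the haemoglobin gene Hbb-bs (−3.86, SE 0.72). H2-Aa, for a chain of MHC class II, fell from 69.6 to 18.4 CPM (−1.92, SE 0.30). Hbb-bs and Tgfbr1 lost the call when one or another library was left out, and Tgfbr1 also with sex as a covariate (adjusted p 0.0732 from labels, 0.0804 from transcripts). The count dropped to 112 without saline knockout 2, 144 without saline knockout 3 and 164 without LPS knockout 3, and to 158 with sex from the labels. The genotypes share no library in these comparisons, and 105 of the 117 genes higher in controls were also higher in knockouts (1.18 by chance), as were 9 of the 11 lower (0.0143 by chance). Both comparisons share the gene dispersions and the filter on low counts, so their calls are not independent. The chance numbers take every tested gene as equally likely to be called.

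**Figure D3:**
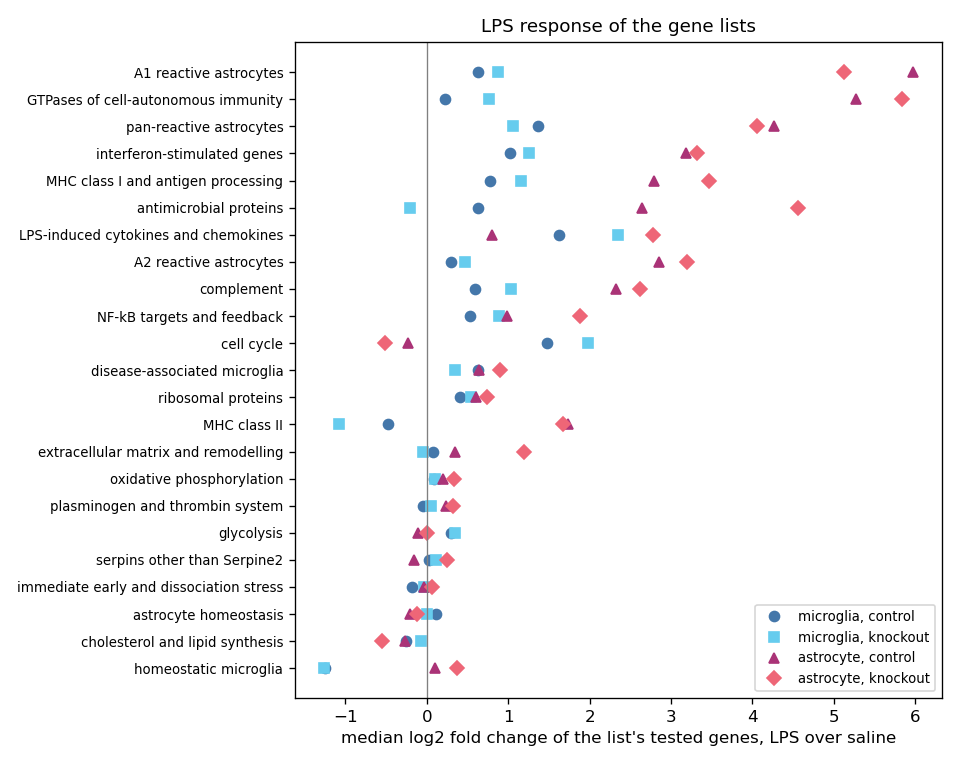
Median log2 fold change, LPS over saline, of each of the 23 gene lists in control and knockout microglia and astrocytes, on a linear axis of log2 units. Interferon-stimulated genes lie between 1.02 and 1.26 in microglia and between 3.18 and 3.32 in astrocytes.

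Among the lists, LPS raised cytokines and chemokines, cell cycle and interferon-stimulated genes in the microglia preparations and lowered homeostatic genes, in both genotypes. The preparations also held neuron markers, at a mean log2 CPM of 7.01 to 7.60 per library. These changes were therefore not shown to be in microglia themselves. Medians were 1.62 in controls and 2.34 in knockouts for cytokines, 1.48 and 1.98 for the cell cycle (20 of 20 higher in controls), and 1.02 and 1.26 for interferon-stimulated genes. Homeostatic genes had a median of −1.26 in both, with 0 of 20 higher in controls. Complement (0.59 and 1.03), MHC class I (0.78 and 1.15), NF-kB targets (0.53 and 0.88) and pan-reactive astrocyte genes (1.36 and 1.06) rose in both. These 8 lists held with an estimated correlation in both genotypes, where the adjusted p lay between 0.00931 and 0.0344. Antimicrobial genes rose in controls (median 0.63, adjusted p 1.03e-22, 0.0116 estimated), where 7 members were called and 11 higher and 2 lower when adjusted over the list alone. Lyz2 rose from 233 to 838 CPM (1.85) there. In knockouts the antimicrobial list was not called (adjusted p 0.0551), and its median (−0.21), mean (0.29) and test (upward) differed in sign, with 11 members higher and 10 lower when adjusted over the list alone. Disease-associated microglia genes held in controls only (0.63, 0.0418 estimated) and lost the call in knockouts (0.35, adjusted p 2.91e-07, 0.0768 estimated). A1 (0.63, 2.38e-05, 0.0509 estimated) and A2 (0.30, 0.0114, 0.0509) astrocyte genes and MHC class II (−0.47, 0.0114, 0.288) held only in knockouts (0.87, 0.48 and −1.08, estimated 0.0245, 0.0415 and 0.0245). Of the lists that held in 1 genotype, the difference between genotypes was called at the preset correlation for antimicrobial (0.0279 estimated) and MHC class II genes (adjusted p 0.449 estimated) and not for the others. Of 17 lists called in each genotype, 10 in controls and 11 in knockouts held.

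Other lists passed with LPS in microglia only at the preset correlation. GTPases of cell-autonomous immunity had medians of 0.23 in controls (adjusted p 0.00739, 0.298 estimated) and 0.76 in knockouts (4.62e-05, 0.151), glycolysis 0.30 (0.000139, 0.165) and 0.35 (0.000395, 0.191), and ribosomal proteins 0.40 (9.75e-08, 0.128) and 0.55 (2.12e-07, 0.135). Cholesterol synthesis was lower in controls (−0.26, adjusted p 0.00876, 0.295 estimated), and in knockouts serpins (0.11, 0.0238, 0.259) and oxidative phosphorylation (0.11, 0.00526, 0.315) were higher. Microglia markers fell at that setting by medians of −0.92 in controls (adjusted p 3.57e-11, 0.205 estimated, and −0.55 without saline control 1) and −0.94 in knockouts (5.6e-12, 0.122, and −0.46 without saline knockout 1), and erythrocyte markers by −2.34 (4.21e-07, 0.181) and −2.86 (1.7e-07, 0.0896). Lymphocyte markers, Gzma among them, were higher in controls (0.22, adjusted p 0.00425, 0.286), a call lost without saline control 1 (−0.07) or LPS control 3 (−0.01). So were monocyte markers (0.23, adjusted p 0.0339, 0.576 estimated), a call lost without saline control 1 (0.13), saline control 3 (0.33) or LPS control 3 (0.25), with a median of 0.37 without saline control 2 and 0.42 without LPS control 1. Neutrophil markers were lower in knockouts (−1.15, adjusted p 1.91e-11, 0.0896 estimated).

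Whether Serpine2 loss changed the microglial LPS response was tested as the difference between the genotypes' responses, which uses the saline knockout libraries of the comparison above once more. Camp, Ngp and Ltf, called lower with LPS in knockouts (−1.68 for Ltf), were not called in controls (−0.35 for Camp, −0.05 for Ngp and 0.25 for Ltf). The difference was −2.54 for Camp (SE 0.46), −2.01 for Ngp (SE 0.43), −2.57 for Mpo (SE 0.60), −1.93 for Ltf (SE 0.50) and −1.41 for S100a8 (SE 0.47). For Lyz2 it was 0.01. Over the antimicrobial list 23 of 31 genes were negative, at a median of −0.56, and 9 were called lower when adjusted over the list alone (camera adjusted p 1.22e-20, 0.0279 estimated, 0.323 with fry). With the share of reads outside genes as a covariate the median was −0.63 and the estimated p 0.178. Neutrophil markers gave −0.98 (adjusted p 8.12e-22, 0.0229 estimated). MHC class II genes (−0.49, adjusted p 8.14e-05, 0.449 estimated) and cytokines (0.30, 0.0223, 0.894 estimated) passed only at the preset correlation. Without the 5 neutrophil markers the antimicrobial median was −0.27 and the estimated p 0.229. EdgeR called 0 genes, with 251 at an unadjusted p under 0.05, and DESeq2 called 1, Camp.

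In astrocytes Serpine2 was the only gene edgeR called between knockout and control in saline (500 at an unadjusted p under 0.05, 2 called by DESeq2), in LPS (497, 1) and averaged (540, 1). In simulated data edgeR recovered 3.33%, 4.84% and 25.4% of 2-fold changes in these 3 comparisons, so changes of that size elsewhere are not excluded. In saline, oligodendrocyte genes were lower in knockout preparations, with 0 of 10 markers higher (n = 3 libraries per group, median −0.72, camera adjusted p 2.4e-12, 0.0613 estimated, 7 called when adjusted over the list alone, and −0.42 without saline knockout 3). Oligodendrocyte precursor markers were not called (−0.46, adjusted p 0.05), though they passed with the replicate block (below). None of the 23 lists was called in saline, and antimicrobial genes, 22 tested, had a median of 0.01 (adjusted p 0.863). After LPS, cytokines (0.69, adjusted p 0.0335, 0.564 estimated) and NF-kB targets (0.57, 0.0335, 0.967) were higher and cell cycle genes lower (−0.30, 0.0335, 0.564), and endothelial markers were higher, 10 of 10 (0.90, 0.000247, 0.435). The endothelial call was lost without LPS knockout 2 (0.40, adjusted p 0.148), and the difference in mean log2 CPM, 0.93 (exact permutation p 0.3), was then 0.51. Antimicrobial genes had a median of 0.27 there (adjusted p 0.135), and MHC class II a median of 0.26 with a mean of −0.20 and a test downward. Averaged over both injections, glycolysis alone was called (0.20, adjusted p 0.0234, 0.901 estimated), with antimicrobial genes at 0.20 (0.282), endothelial markers at 0.67 (0.000654, 0.35, lost without saline knockout 1 or LPS knockout 2) and oligodendrocyte markers at −0.48 (1.13e-10, 0.0915).

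Knockout and control LPS astrocytes with the same number deviated together, and in that comparison the paired fit called more lists. With the replicate block 9 lists passed at the preset correlation and 0 at the estimated one, among them antimicrobial genes (adjusted p 0.0155, 0.535 estimated), GTPases (0.00729, 0.629), pan-reactive genes (0.0151, 0.629), MHC class I (0.00793, 0.629), extracellular matrix (0.00537, 0.535) and glycolysis (0.0361, 0.629). Oligodendrocyte markers, at a median of −0.31 with the block, were called lower at the preset correlation (adjusted p 0.00601, 0.525 estimated). Unpaired, the antimicrobial list passed without LPS control 2 (adjusted p 0.0046) and without LPS knockout 3 (0.00541).

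LPS raised reactive and interferon genes in the astrocyte preparations. In controls Lcn2 rose 153-fold, from 4.62 ± 0.367 CPM (log2 7.26, SE 1.24, SD, n = 3), and the protease inhibitor gene Serpina3n to 967 ± 721 CPM (6.45, SE 0.88), both markers of reactive astrocytes. The chemokine gene Cxcl9 rose 173-fold (7.43, SE 1.42), with Saa3 (6.98), Isg15 (6.88), Nlrc5 (6.53), Ifi44 (6.43), H2-T23 (6.20), Fkbp5 (6.18) and Oasl2 (6.08), and the astrocyte filament gene Gfap rose from 85.8 ± 11.3 to 623 ± 382 CPM (2.86, SE 0.46). Myoc fell by 4.52 (SE 0.86), with Ednra (−1.87), the oligodendrocyte gene Opalin (−1.86), Tnc (−1.77), Grin3a (−1.72), Sned1 (−1.72), Plekhh1 (−1.67), Map6d1 (−1.66), Mapt (−1.61) and Lpar1 (−1.51). EdgeR called 141 genes higher and 28 lower. In knockouts 245 were higher and 38 lower, led by Ccl5 (7.63), Lcn2 (7.39, 771 ± 379 against 4.56 CPM), Saa3 (7.34), Marco (7.22), Cxcl9 (6.82), Serping1 (6.32), Ifit1 (6.22), Serpina3n (6.19), H2-T23 (5.99) and Oasl2 (5.92). Rpe65 (−3.52), Fezf2 (−2.53), Sned1 (−1.97), Dctd (−1.97), Fam184b (−1.89), Gdf10 (−1.83), Rgs16 (−1.78), Ccn1 (−1.53), Vegfa (−1.45) and Celsr1 (−1.42) fell. The genotypes' calls, from separate libraries but with shared dispersions, had 105 higher genes in common (1.9 by chance) and 7 lower (0.0585 by chance), with the same limits as in microglia.

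The third LPS library of each genotype had the lowest interferon-stimulated expression of its group, and the calls in astrocytes hung on single libraries. Over 37 interferon-stimulated genes the mean log2 CPM of the LPS libraries was 3.86, 3.24 and 2.91 in controls and 4.65, 3.39 and 2.21 in knockouts, against −0.02 to 0.33 in all saline libraries. Lcn2 stood at 1062, 1036 and 27.0 CPM in the LPS controls. In the LPS knockouts it averaged 771 ± 379 CPM (SD, n = 3), a spread that leaves no library as low as 27.0. Calls in controls were 38, 36 and 43 without saline control 1, 2 and 3, 74 and 55 without LPS control 1 and 2, and 476 without LPS control 3. In knockouts they were 48, 53 and 38 without saline knockout 1, 2 and 3, 140 without LPS knockout 2 and 561 without LPS knockout 3. Of the 20 genes named in controls only H2-T23 and Oasl2 kept the call whichever library was left out, and of the 20 in knockouts H2-T23, Oasl2, Sned1 and Ccn1 did. A fit of only the groups compared ended the call of Lcn2 (adjusted p 0.154), Cxcl9 (0.161), Saa3 (0.0673), Serpina3n (0.0641), Fkbp5 (0.0642) and Mapt (0.0577) in controls and of Ifit1 (0.0574), Dctd (0.0702), Rgs16 (0.0745) and Celsr1 (0.0519) in knockouts. Their fold changes hardly moved, with a log2 of 7.45 for Cxcl9, 6.47 for Serpina3n and −1.59 for Mapt in that fit. With the share of reads outside genes as a covariate, Cxcl9 (0.0746), Lcn2 (0.0554), Myoc (0.0524), Mapt (0.0578) and Lpar1 (0.0578) missed the threshold in controls (Lcn2 at 6.93), as did Marco (0.0521), Cxcl9 (0.0627), Ifit1 (0.0531) and Fam184b (0.05) in knockouts. Ifit1 missed it also with RLE factors (0.0512) and the replicate block (0.0733). With that covariate fold changes moved little, with a log2 of 7.44 for Cxcl9, −4.62 for Myoc and −1.54 for Mapt in controls. In knockouts Ifit1 was at 6.05 and Fam184b at −1.82.

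**Figure D4:**
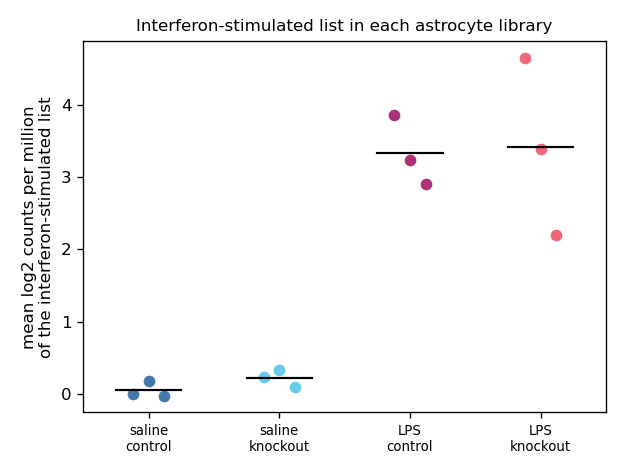
Mean log2 CPM of the 37 interferon-stimulated genes in each of the 12 astrocyte libraries, each point a library and each bar the mean of 3. The third LPS libraries, at 2.91 in control and 2.21 in knockout, lie lowest of their groups and above all saline libraries.

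The same preparations showed rises of many lists, beside rises of markers of other cell types given below. In controls and knockouts, A1 reactive genes rose at medians of 5.97 and 5.13, pan-reactive genes at 4.27 and 4.06, interferon-stimulated genes at 3.18 (37 of 37 higher) and 3.32, MHC class I at 2.80 and 3.47, complement at 2.33 and 2.62 and MHC class II at 1.73 and 1.67. Antimicrobial genes rose at 2.65 in controls, with 8 called and 14 adjusted over the list alone (adjusted p 9.15e-19, 0.00898 estimated), and at 4.56 in knockouts with 12 called (4.87e-21, 0.0107 estimated). Those 7 lists held with an estimated correlation in both genotypes, at adjusted p up to 0.0421. In knockouts cytokines (2.77, 0.0142 estimated), disease-associated microglia genes (0.90, 0.0302), extracellular matrix (1.19, 0.0302), plasminogen and thrombin genes (0.32, 0.041) and serpins (0.24, 0.041) held as well. In controls serpins had a median of −0.16, a mean of 2.19 and an upward test (adjusted p 0.00715, 0.106 estimated). Cytokines (0.81, 0.000102, 0.0825 estimated) and disease-associated genes (0.64, 1.33e-06, 0.0674) passed there at the preset correlation alone. GTPases (5.28 and 5.83, estimated 0.106 and 0.089), NF-kB targets (0.99 and 1.88, 0.346 and 0.197), A2 genes (2.86 and 3.20, 0.187 and 0.155), ribosomal proteins (0.61 and 0.74, 0.213 and 0.127) and cholesterol synthesis (−0.26 and −0.54, 0.213 and 0.0921) did not hold in controls or knockouts. With the replicate block, a common effect per number over all astrocyte libraries, the GTPases held in knockouts (0.0349). Cell cycle genes were lower in knockouts (−0.51, adjusted p 0.0137, 0.197 estimated). Camera called 15 lists in controls and 18 in knockouts, of which 7 and 12 held, and the difference between genotypes was called for cytokines alone, at the preset correlation only (adjusted p 0.639 estimated).

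Markers of other cell types also moved in the LPS astrocyte preparations. Endothelial markers were higher at medians of 1.70 in controls (camera adjusted p 1.02e-07, 0.122 estimated) and 2.77 in knockouts (1.09e-10, 0.0504), and pericyte markers at 1.52 (0.00307, 0.122) and 2.01 (0.000496, 0.0504, and 1.04 without LPS knockout 2). Mean log2 CPM of the 3 neutrophil markers detected was higher by 2.09 in controls and 2.59 in knockouts (1.56 without LPS knockout 2), and of the 3 monocyte markers by 1.48 and 1.86 (exact permutation p 0.1 each), so the rises of antimicrobial, MHC class II, complement, cytokine and disease-associated genes were not shown to be in astrocytes themselves. Border macrophage markers (1.69, 0.00874, 0.177 estimated) and neuron markers (0.72, 0.0402, 0.276) were higher in controls and oligodendrocyte markers lower (−0.69, 3.36e-05, 0.177). Neuron (0.75, 0.0125, 0.337) and oligodendrocyte precursor markers (1.21, 0.0244, 0.412) were higher in knockouts. The border macrophage, neuron and precursor calls were each lost without LPS control 2 or LPS knockout 2 of their comparison.

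The astrocytic LPS response was not shown to depend on Serpine2 for any single gene, since edgeR called 0 genes in the difference (473 at an unadjusted p under 0.05, 0 called by DESeq2). Cytokines differed at a median of 1.32, higher in knockouts (adjusted p 0.0028, 0.639 estimated), and antimicrobial genes did not pass (0.27, 0.537). Oligodendrocyte (0.36, adjusted p 0.00445) and oligodendrocyte precursor markers (0.85, 0.0215) passed at the preset correlation and not the estimated one (0.628 for both). Both lost the call without saline knockout 3 (adjusted p 0.41 and 0.372), and without LPS knockout 2, where the precursor median was −0.16.

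Whether the knockout effect differed between microglia and astrocytes, the contrast of the series title, was tested directly. Antimicrobial genes, 33 tested, had a median difference of 1.05 in saline, higher in microglia, and did not pass (adjusted p 0.476, 0.966 estimated), and after LPS the median was −0.53 (0.979). The saline contrast is one in which camera missed a shifted list in simulated data. No list passed in saline, and after LPS cell cycle genes alone did (0.87, adjusted p 9.48e-07, 0.26 estimated). Oligodendrocyte markers differed in saline (0.66, adjusted p 0.000379, 0.948 estimated), a call lost without any 1 of 3 libraries, astrocyte saline knockout 3 (0.40, 0.22) among them, and ependymal and choroid plexus markers, tested only here with 5 genes, did not pass (0.46, 0.904). EdgeR called 0 genes in saline, with 1394 at an unadjusted p under 0.05 against 1230 by chance, and 0 after LPS, with 1280, and DESeq2 called 1 and 2. Between the LPS responses of the cell types, which were not tested against each other, 23 of 96 microglial and 131 astrocytic genes were higher in both controls among the 16972 genes tested in both (0.741 by chance), Lcn2, Lyz2, C3 and Saa3 among them. In knockouts 44 were shared (2.54 by chance), and 0 lower genes were shared in either genotype.

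Mean marker levels per library were compared without a model. They are RNA levels and not shares of cells, and can also move with expression within a cell type. Neutrophil markers averaged a log2 CPM of 5.81 ± 0.31 in saline knockout microglia and 4.84 ± 0.12 in saline controls (SD, n = 3 each, exact permutation p 0.1, two-sided), and monocyte markers 4.19 ± 0.27 against 3.49 ± 0.25 (exact p 0.1). After LPS the neutrophil means were 4.82 ± 0.62 in knockout and 4.94 ± 0.28 in control microglia (difference −0.12, exact p 0.9). Oligodendrocyte markers averaged 7.09 ± 0.48 in saline knockout astrocytes and 7.82 ± 0.12 in controls (difference −0.73, exact p 0.1), and the difference was −0.45 without saline knockout 3. Of 104 such tests 30 reached the smallest p of 0.1, with an adjusted p of 0.347, so none passed. Groups of 3 against 3 with no effect fail to overlap in 10% of tests.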

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

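The tests of neutrophil RNA, of a lower microglial share, of exchanged libraries and of genomic DNA, and all values with camera on cell type markers, were chosen after the results had been seen. The share of reads outside genes was chosen as a covariate after the data had been seen, though its test was written before its result. The other tests were written beforehand.

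Antimicrobial genes were higher in saline knockout microglia (median log2 0.91) and lower in the difference of LPS responses, where the genotypes differed by −0.56. A lower share of microglial RNA would raise the markers of every other cell type alike, which oligodendrocyte markers (−0.026) beside neutrophil markers (1.13) argue against, and with the share of reads outside genes as a covariate the list stayed at 0.94, and in the difference it was at −0.63 but lost its call at the estimated correlation (adjusted p 0.178, from 0.0279). RNA of neutrophils in the saline knockout preparations is a candidate source, since the 7 neutrophil markers outside the list had a median of 0.93, and S100a8 and S100a9, the most abundant neutrophil genes, stood at 510 and 570 CPM against 187 and 230 in controls. Perfusion and immunopanning were not shown to remove such cells, and S100a8 stood at 187 CPM in controls too. Of the neutrophil markers only Csf3r (log2 −0.10) did not move with the rest. Of the 31 genes, 5 are themselves neutrophil markers and Chil3 is a monocyte marker. The 26 members outside the neutrophil markers still include Lcn2, Mpo and other genes of neutrophils, so they are not independent of such cells. How much of the pattern neutrophils account for therefore stays open. An effect of Serpine2 loss on microglia themselves was not tested and stays open too, and in the difference neutrophil markers changed by −0.98, with 9 antimicrobial genes lower when adjusted over the list alone.

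The third LPS astrocyte library of both genotypes had the lowest mean interferon-stimulated expression of its group. LPS control 3 (2.91) lay close below LPS control 2 (3.24), and LPS knockout 3 (2.21) further below LPS knockout 2 (3.39). An exchange with a saline library is argued against, since the lowest LPS library lay 1.87 log2 units above the highest saline library in mean interferon-stimulated expression, where saline libraries spanned 0.35. Depth is argued against as well for LPS knockout 3, since thinning the other LPS libraries to the lowest depth moved that mean by at most 0.0252. LPS knockout 3 lay 1.58 below the average of those other libraries, and the gap of LPS control 3 was not set against thinning. These are the only LPS astrocyte libraries from females, and the names of the deposited tables carry a number that may stand for a day and that sets these libraries apart, so sex and day of preparation stay open and untested.

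A larger share of microglia reads lay outside annotated genes, a median of 64.0% against 20.7% in astrocytes, in reads that no comparison used. Counting by strand of libraries that do not mark strand is argued against by genes nested in exons of the other strand, whose ratio of counts per base to their hosts had a median of 0. Genomic DNA is argued against by olfactory and vomeronasal receptor genes, which are hardly read in brain and whose exons held 0.0369 of the reads per base found outside genes (0.0284 to 0.0434 over libraries), where DNA would cover both alike. For an annotation with fewer genes, identifiers absent from the microglia tables held 19.1% of astrocyte gene counts. The single gene CT010467.1 held 18.2% and the rest of them 0.908%. As far as astrocyte counts stand in for microglial reads, that argues against missing genes other than CT010467.1 as the source. For CT010467.1 this cause cannot be told apart from others, and cell type goes together with region, preparation and annotation here. The most counted microglia identifier, ENSMUSG00000119584 with 5.12% of gene counts, had no symbol in the reference table. Whether it stands for the same RNA as CT010467.1 was not checked. No biological explanation was tested in this part.

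Further differences between groups were found by testing the difference itself, all at the preset correlation, where other splits of the libraries gave as many gene lists (below), and none at the estimated one. In microglia, the LPS responses of cytokines differed by 0.30 and of MHC class II genes by −0.49 between knockouts and controls. In astrocytes, the responses of cytokines differed by 1.32, of oligodendrocyte markers by 0.36 and of oligodendrocyte precursor markers by 0.85 (−0.16 without LPS knockout 2). The knockout effect on oligodendrocyte markers in saline was higher by 0.66 in microglia than in astrocytes, and that on cell cycle genes after LPS by 0.87. The oligodendrocyte and precursor calls were lost without one or another library.

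Other splits of the same libraries show how many calls a grouping without meaning can give. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 128 genes for LPS in control microglia, 254 in knockout microglia, 169 in control and 283 in knockout astrocytes, and the highest other split called 0 in each, so that 1 of 10 splits called as many. For knockout against control the counts were 0 in saline and 0 in LPS microglia (highest other 0, 10 of 10 splits as many), 1 in saline astrocytes (highest other 0, 1 of 10) and 1 in LPS astrocytes (highest other 511, 4 of 10). The split with 511 calls points to a structure among the LPS astrocyte libraries, and the 3 other splits that part all pairs of equal number called 0. Averaged over injections, 2 of 60 splits called as many as the 1 gene in microglia, but that gene is Serpine2, whose loss defines the groups, and another split called 168 genes, a structure again, so the count shows no difference beyond Serpine2. In astrocytes 6 of 60 splits, made without regard to pairs, called as many as the 1 gene, Serpine2 again (highest 32). Of the other splits, 5 of the 36 that part 1 LPS pair did and 0 of the 23 that part all 3. For differences, all 60 splits in microglia (highest 1) and all 60 in astrocytes (highest 190), and all 40 between the cell types in saline (highest 1) and in LPS (highest 89), called at least the real 0, which any split does, so these counts say nothing about chance. The antimicrobial median in saline microglia, 0.91, was matched by 1 of 10 splits, the real one, with 0.49 the highest other, and the size of the difference, 0.56, by 12 of 60 with 1.19 the highest, which does not exclude chance. At the preset correlation other splits called many gene lists too. Knockout saline microglia had 7 lists against up to 10, LPS 11 against up to 15, their mean 8 against up to 17 and the difference 3 against up to 17, with 53 of 60 splits giving as many. Knockout astrocytes had 0 lists in saline against up to 4, LPS 3 against up to 16, their mean 1 against up to 16 and the difference 1 against up to 18 (52 of 60 as many). Between the cell types there were 0 lists in saline against up to 7 and 1 after LPS against up to 17 (37 of 40 as many). LPS responses had 17 against up to 18 and 17 against up to 16 in microglia, and 15 against up to 19 and 18 against up to 15 in astrocytes. At the estimated correlation those LPS responses had 10, 11, 7 and 12 lists against 0 in every other split, knockout saline microglia 1 against 0 and the difference 1 against up to 2.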

How the results depend on the processing

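The covariates for reads outside genes, neutrophil score and sex from transcripts, the list without neutrophil markers, the astrocyte fit without the third LPS library of both genotypes, and camera and scores of cell type markers with each library left out were chosen after the data had been seen. One call had its test reversed, that of oligodendrocyte precursor markers in the astrocyte difference (below). Without 1 library 4 called marker lists, this one included, had medians that changed sign, as did 45 of 104 differences of marker scores, none of which could pass a test. RLE factors and the stricter filter moved no count by over 1.5 times, and the cause of the changes that follow was not tested. In the order saline, LPS, mean, LPS in controls, LPS in knockouts and difference, DESeq2 called 1, 1, 4, 285, 515 and 1 genes in microglia. It called 2 in saline knockout astrocytes, 639 (479 higher) and 827 (635 higher) for LPS in control and knockout astrocytes, and 1 in saline and 2 in LPS between cell types. With no filter on low counts, microglia gave 22, 19, 40, 463 (362 higher), 637 and 7 in that order, astrocytes 8, 26, 9, 804, 1027 and 13, and the cell types 76 and 44. Microglial Serpine2 then passed in saline and LPS with no filter (−1.78 and −1.92) and with DESeq2 (−1.79 and −1.90). With the share of reads outside genes as a covariate, LPS calls in microglia were 268 in controls and 447 (338 higher) in knockouts, and knockout LPS microglia had 1, Serpine2 (−1.86). Sex from the labels gave 158 calls for LPS in knockout microglia and 295 in control astrocytes, and sex from transcripts 163 in the former. The replicate block gave 286 (216 higher) for LPS in control astrocytes, and a fit of only the groups compared gave 349 there and 184 in knockouts. Without the third LPS astrocyte library of both genotypes the counts were 734 (485 higher) in controls and 912 (648 higher) in knockouts, of which 165 and 273 were among the calls with all libraries. The antimicrobial list kept the direction of its test in the comparisons that had called it. Its adjusted p in microglia was 0.0787 with fry in saline, 0.435 for the mean and 0.323 for the difference. At the estimated correlation it was 0.0833 for the mean, and 0.452, 0.597 and 0.346 (saline, mean, difference) with the neutrophil score as a covariate. It was 0.134 and 0.178 (mean, difference) with the share of reads outside genes, and 0.0802 and 0.229 without the neutrophil markers. In saline the list kept its call at the estimated correlation in either case, with a median of 0.82 without the neutrophil markers. In knockout LPS astrocytes it passed with the replicate block (0.0155). In that paired fit oligodendrocyte markers passed as well (0.00601), and elsewhere, where numbers are not shown to mark pairs, 5 other marker results did, oligodendrocyte in LPS knockout microglia (0.0311), precursors in saline astrocytes (0.0016, where names of the tables share a number within pairs) and between cell types in saline (0.0244), and microglia and endothelial markers between cell types in LPS (0.036 each).

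Leaving out each library in turn, knockout microglia had 0 to 1 calls in saline, 0 to 1 in LPS and 1 to 1 in the mean, and 0 to 1 in the difference. LPS gave 89 to 134 calls in control and 112 to 215 in knockout microglia, 36 to 476 in control and 38 to 561 in knockout astrocytes, and 1 each for knockout astrocytes. Serpine2 ran from −1.98 to −1.49 in saline and from −2.09 to −1.67 in LPS microglia. The adjusted p of the antimicrobial list ran from 0.00434 to 0.919 in knockout LPS microglia and from 0.0046 to 0.78 in knockout LPS astrocytes, and its median in saline from 0.76 to 1.03. For the 76 pairs of a named gene and a comparison, 970 of 1139 recomputed calls were the same, 169 were lost and 0 reversed. Of the marker lists, 1230 recomputed values were the same, 67 stronger, 46 weaker and 1 reversed. That one, precursor markers in the astrocyte difference (0.85), ran in adjusted p from 5.04e-06 without LPS knockout 1 to 0.965 without LPS knockout 2, where its median was −0.16. EdgeR recovered at most 15.2% of simulated 2-fold changes between 3 and 3 libraries and 54.5% for the microglia mean over both injections, which has the same depth and more libraries, and depth was not varied.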

Other observations

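The test of neuronal RNA was chosen after the result had been seen, and the abundances come from a table of the most abundant genes, chosen after its values were seen.

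The microglia preparations held transcripts that neurons make in quantity. Meg3 took 0.471% of gene counts in microglia libraries, Snhg11 0.447%, Rian 0.272% and Syne1 0.234%, all among the 10 most abundant genes, beside 0.199% for the cystatin gene Cst3, which microglia express strongly. Malat1 took 1.69%, mt-Rnr2 2.47% and ENSMUSG00000119584, the most counted identifier, 5.12%. In astrocyte libraries Slc1a2, the glutamate transporter of astrocytes, took 1.06% and Sparcl1 0.327%, and mt-Rnr2, CT010467.1 and mt-Rnr1 took 19.0%, 18.2% and 16.8%.

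Erythrocyte markers of microglia differed by −1.78 in controls and −2.09 in knockouts between LPS and saline in mean log2 CPM (exact permutation p 0.1 each, two-sided, n = 3 per group, adjusted p 0.347). In the astrocyte preparations mean marker levels were higher after LPS for endothelial cells by 1.98 and 2.62 in controls and knockouts, for monocytes by 1.48 and 1.86, for neutrophils by 2.09 and 2.59 (1.56 without LPS knockout 2) and for vascular fibroblasts by 0.53 and 1.29, all at the smallest exact p of 0.1. In control astrocytes Serpine2 had a log2 fold change of −0.67, LPS against saline (edgeR unadjusted p 0.0121, not called after adjustment).

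RNA of neuronal nuclei and debris may be what raised the share of microglia reads outside genes. Neuron markers averaged a log2 CPM of 7.01 to 7.60 in microglia and 1.72 to 3.25 in astrocyte libraries, which goes with the hypothesis, though region and preparation differ too. Libraries with more neuron markers would then have a larger share, and the opposite was found over the 12 microglia libraries, with a Pearson r of −0.777 (permutation p 0.00353, adjusted 0.00706) and a Spearman rho of −0.727 (permutation p 0.00927, adjusted 0.00927). Without the 2 libraries farthest from the median r was −0.401, and within injections it was −0.986 in saline and −0.792 in LPS, so its size rests in part on those 2 libraries. A negative r was the outcome set against the hypothesis, so by that criterion the trend counts against it among the microglia libraries. The marker levels of the cell types go the other way. A trend over so narrow a range of marker levels does not test the difference between cell types, for which the hypothesis stays open.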
